A study of Mus musculus with 19 samples.

How the data were processed

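RNA from purified mouse CD8 T lymphocytes was measured on 19 Affymetrix mouse gene arrays, each from 0.125 µg of RNA. The deposited values are log2 signals per probe set, 35557 probe sets on each array, and they were used as deposited. The submitters' processing notes name Affymetrix Expression Console; its version, and the summarization and normalization it was run with, are not given in the sources used here. That the values are on a log2 scale was read from their range, which ran from about 3 to 15 on every array. Array medians lay between 7.69 and 7.89. For arrays, the number of arrays limits the precision.

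Arrays were grouped by their labels into naive cells (n = 4), control effector cells after 72 h of activation (n = 4), Stat5ca cells at 72 h (n = 2), control cells after transfer (n = 2), Stat5ca cells after transfer (n = 4) and T-betKO Stat5ca cells after transfer (n = 3). The labels do not say whether arrays of a group came from separate animals or cultures, so p-values measure the spread between these arrays. No numbering links arrays of different groups, and no pairing was used.

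Each gene was represented by its brightest probe set over all arrays. Of the probe sets, 21789 carried 1 gene, 1621 carried several and 12147 carried none. This left 19938 genes, 999 of them with more than 1 probe set. Olfactory and vomeronasal receptor genes (1190) served as a guide to the signal of genes that are not expressed; their 95th percentile was 7.32. For named genes with a group mean under this level, the change is also given counted from 7.32, a step added after the values were seen.

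Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance), without covariates. The first 7 comparisons used the 16 TCRP1A arrays in 1 fit, so that groups of 2 shared a spread with the others; the T-betKO comparison used all 19 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors of log2 changes are standard errors from limma, and errors of group means are SD.

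The groups, the comparisons, the test, 25 gene lists and the rule for naming genes were chosen before the data were examined. The rule takes the 8 largest rises and 8 largest falls of each comparison among called genes whose groups do not overlap in any array (without that condition for the difference between the Stat5ca effects), up to 4 called members of each list, and Stat5a, Stat5b, Tbx21 and Eomes in every case. Of 479 list members, 430 were measured. Lists were tested with camera, which compares a list with all other genes, using a correlation between genes estimated from the data and adjusting over all 200 tests. Camera with a preset correlation of 0.01 and fry were run beside it. The direction test of fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes.

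Alternatives planned beforehand were a 2-fold minimum, another model of the spread, other sets of arrays in the fit, quantile normalization, centring on array medians, leaving out dim genes, averaging probe sets, array weights, the RNA integrity number as a covariate, and leaving out each array in turn. After the data were seen, 5 more were added: the myeloid marker level as a covariate, the sex of the cells as a covariate, and fits without naive arrays 34 and 36, without naive arrays 33 and 35, and without T-betKO arrays 39 and 40. Calls were tested on simulated data with known changes, made without the correlations or unequal spreads of real arrays. For Stat5ca against control after transfer, 37.3% of genes with a simulated change of 0.5 were called, 85.1% at 1 and 97.0% at 2, and 6 of 19702 unchanged genes were called. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9. Array images were not used, because only the processed values were at hand.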

Results

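The arrays measured gene expression in CD8 T lymphocytes from mice. Of the 19 arrays, 16 came from TCRP1A cells, which carry a transgenic T-cell receptor on a Rag-1-deficient B10.D2 background. They covered naive cells (n = 4), control effector cells after 72 h with their antigen (n = 4), effector cells carrying Stat5ca, a constantly active Stat5, at 72 h (n = 2), and both kinds of cell recovered after transfer into congenic hosts. By the labels, control cells were recovered on days 18 and 120 (n = 2) and Stat5ca cells on day 20 (n = 4), while the series description puts recovery later than day 20. A further 3 arrays held Stat5ca cells lacking T-bet, the factor encoded by Tbx21, on days 14, 14 and 54. The labels give the T-betKO cells a C57BL/6 strain beside a B10.D2 background, a stimulus with antibodies to CD3 and CD28 in place of antigen, and another labelling protocol.

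Control effector cells at 72 h (n = 4) were compared with naive cells (n = 4), which shows what activation changed. Gzmb, encoding the killer protease granzyme B, rose by 5.03 ± 0.29 on the log2 scale (SE), from 8.03 ± 0.82 to 13.06 ± 0.35 (SD). All 36 measured cell-cycle genes rose and 0 fell (36 and 0 adjusted over the list alone, adjusted p = 0.250 with an estimated correlation). Bub1 of the spindle checkpoint rose by 4.24 ± 0.45 and Top2a by 3.95 ± 0.45. All 17 cholesterol-synthesis genes rose (17 adjusted over the list alone, adjusted p = 0.280 with an estimated correlation). Cyp51 rose by 2.41 ± 0.14. Of the glycolysis genes, 14 of 16 rose while 0 fell (14 and 0 adjusted over the list alone, adjusted p = 0.0614 with an estimated correlation), with Tpi1 up by 2.69 ± 0.17. Of 22 interferon-stimulated genes, 19 fell, 0 rose and 3 were not called (21 fell adjusted over the list alone, adjusted p = 0.280 with an estimated correlation), Ifit3 by −4.40 ± 0.21 and Ifit1 by −3.45 ± 0.22. Bub1 in naive cells and Ifit3 at 72 h lay under the background of 7.32, and counted from it they changed by 4.13 and −4.39.

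The inhibitory receptor genes Pdcd1 (3.77 ± 0.29) and Ctla4 (3.42 ± 0.23) rose with activation, as did Tbx21 (2.56 ± 0.12), Eomes (1.85 ± 0.36) and Il2ra, the high-affinity interleukin-2 receptor chain (4.04 ± 0.29). Ccr9, a gut-homing receptor, changed by −5.29 ± 0.33 and Il6ra by −3.40 ± 0.15. Of 24 cytotoxic genes, 12 rose, 2 fell and 10 were not called (12 and 3 adjusted over the list alone, adjusted p = 0.273 with an estimated correlation). Myeloid marker genes averaged 8.00, 11.42, 8.80 and 11.17 in the naive arrays 33, 34, 35 and 36, and 8.33 to 8.91 in the effector arrays. Adgre1, a macrophage marker, changed by −2.50 ± 0.87, and by −0.43 with an adjusted p of 0.522 without naive arrays 34 and 36. It no longer passed without naive array 34 (−1.77) or 36 (−1.85) or control array 2 (−2.22) or 3 (−2.27). At 72 h Ccr9 and Adgre1 lay under background, and counted from it the changes were −4.91 and −2.28. In all, 4378 genes rose and 4956 fell, around a median change over all genes of −0.0890. The balance turned with arrays centred on their medians (4575 rose, 3776 fell) and without dim genes (4312 and 3524). Of the 9334 genes, 1425 changed at least 2-fold, 956 up and 469 down.

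**Figure D1:**
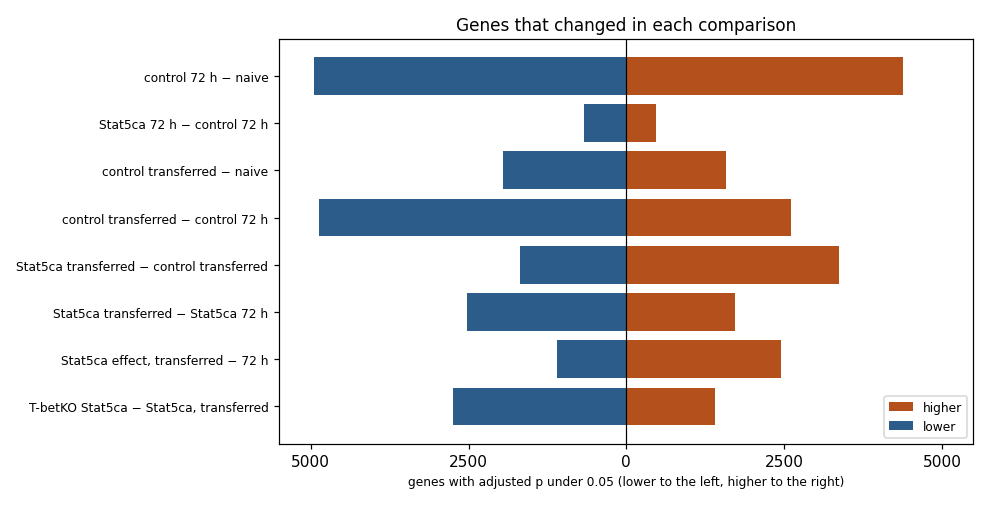
Number of genes with an adjusted p under 0.05 in each of the 8 comparisons, with genes higher in the first group to the right and genes lower to the left. The comparison of control effector cells with naive cells has 4378 higher and 4956 lower, and that of Stat5ca with control cells at 72 h has 472 higher and 668 lower.

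Stat5ca cells (n = 2, sorted for GFP per the labels) were compared with control cells (n = 4) at 72 h for the effect of active Stat5 in effector cells. By the labels the Stat5ca cells were transduced, while no transduction or GFP is named for the control cells. Active Stat5 can therefore not be told apart from transduction, here or after transfer, nor from selection by GFP at 72 h. Stat5a rose by 1.50 ± 0.13, from 10.56 ± 0.04 to 12.06 ± 0.09, while Stat5b differed by 0.10 ± 0.12 (adjusted p = 0.699). Of 26 STAT5 target genes, 5 rose, 2 fell and 19 were not called (11 and 2 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 1.52 ± 0.34 and Pim1 by 1.37 ± 0.25. Klf2 (1.51 ± 0.22) and S1pr1 (1.02 ± 0.13), which govern exit from lymphoid tissue, were among 4 of 19 naive and central-memory genes that rose, with 0 fallen (8 and 1 adjusted over the list alone, adjusted p = 0.288 with an estimated correlation). Foxp3, a regulatory T-cell factor, rose by 1.37 ± 0.11. Socs3 and Pim1 no longer passed without Stat5ca array 9 (1.71 and 1.21) or 10 (1.32 and 1.54).

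Among genes that fell with Stat5ca at 72 h were Gzmc (−2.54 ± 0.33), the chemokine gene Xcl1 (−2.15 ± 0.44) and Pdcd1 (−2.14 ± 0.36). Of 36 cell-cycle genes, 9 fell and 0 rose (15 and 0 adjusted over the list alone, adjusted p = 0.334 with an estimated correlation), and of 16 glycolysis genes 5 fell and 0 rose (8 and 0 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), Hk2 by −1.27 ± 0.27. Lyz2, which encodes lysozyme of myeloid cells, changed by −5.59 ± 0.60 and H2-Ea, an MHC class II gene, by −4.29 ± 0.49. Counted from background, under which Gzmc, Lyz2 and H2-Ea lay in Stat5ca cells, the changes were −1.85, −4.60 and −3.79. Xcl1 (−1.79), Pdcd1 (−2.16) and Hk2 (−0.84) no longer passed without Stat5ca array 10. Myeloid marker genes averaged 7.44 and 7.41 in the Stat5ca arrays against 8.33 to 8.91 in the controls. Of 1140 genes, 472 rose and 668 fell. The count was 98 without Stat5ca array 10, 463 without Stat5ca array 9, 591, 616 and 1794 without control arrays 1, 4 and 3, and 4604 with array weights.

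**Figure D2:**
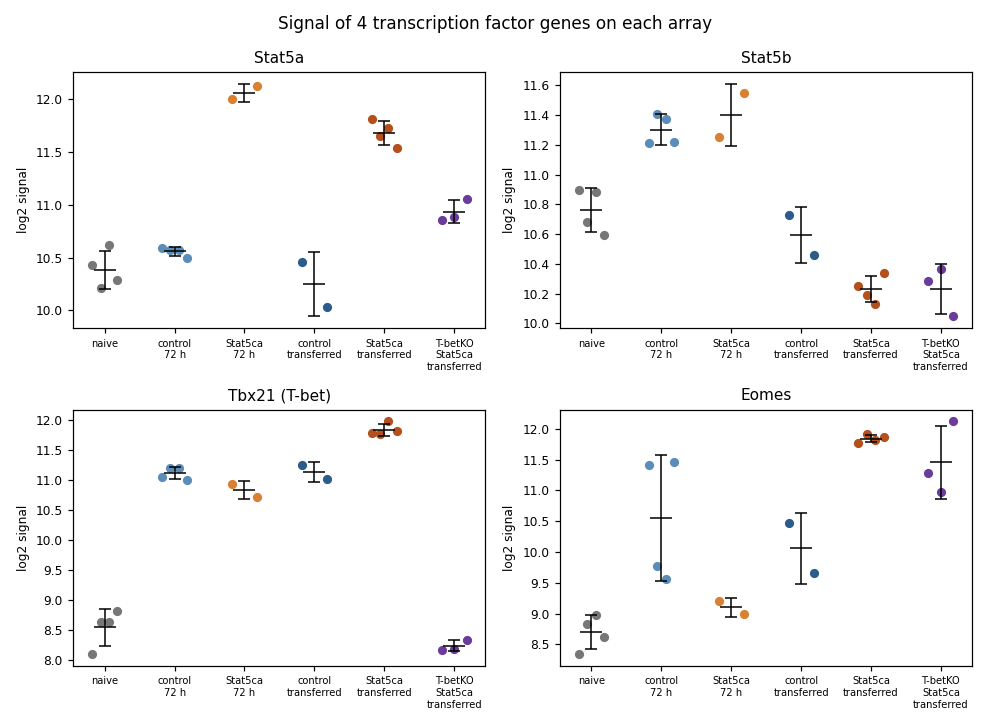
Log2 signal of Stat5a, Stat5b, Tbx21 and Eomes on each array by group; points are arrays, horizontal ticks are group means and bars are SD. Stat5a averages 12.06 in Stat5ca cells at 72 h and 10.56 in controls, and Tbx21 averages 8.24 in T-betKO cells against 11.83 in Stat5ca cells after transfer.

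Control cells after transfer (n = 2) were compared with naive cells (n = 4) to show what separates previously activated cells from naive ones. Ifng, encoding interferon gamma, rose by 3.49 ± 0.31, Tbx21 by 2.58 ± 0.15, Fasl by 2.68 ± 0.31 and Gzmb by 2.34 ± 0.35. Of 17 Tc1 factor and receptor genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.0614 with an estimated correlation), including Cxcr3 (2.39 ± 0.19), and 11 of 24 cytotoxic genes rose while 0 fell (12 and 0 adjusted over the list alone, adjusted p = 0.0614 with an estimated correlation). The activating receptor gene Klrk1 rose by 3.15 ± 0.33. Tox, a factor of T-cell development and exhaustion, changed by −2.20 ± 0.18, Lef1, a factor of naive cells, by −1.43 ± 0.13 and Ccr9 by −2.55 ± 0.40. Fasl lay under background in naive cells, and counted from it rose by 2.58.

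Markers of other cells moved in the same comparison: 11 of 13 T-cell identity genes fell and 0 rose (11 and 0 adjusted over the list alone, adjusted p = 0.280 with an estimated correlation), and 9 of 18 myeloid genes rose with 0 fallen (13 and 0 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation). The myeloid list averaged 11.93 and 11.69 in the transferred control arrays. Of 3538 genes, 1583 rose and 1955 fell, around a median change over all genes of −0.12. With arrays centred on their medians 1600 rose and 1549 fell, and of those changed at least 2-fold 647 rose and 95 fell. The count was 840 without the day 120 array, 1586 without the day 18 array, 323 with these groups alone in the fit, 799 with the myeloid level as a covariate, 5767 without naive arrays 34 and 36 and 1718 without naive arrays 33 and 35. Without naive arrays 33 and 35, Eomes no longer passed (1.33, adjusted p = 0.133), nor without naive arrays 34 and 36 (1.40, adjusted p = 0.0580). Of 84 named results, 37 lost their call with the myeloid covariate, 17 without naive arrays 33 and 35, 3 without 34 and 36, 16 with the sex of the cells as a covariate and 13 with the RNA integrity number.

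Control cells after transfer (n = 2) were also compared with control effector cells at 72 h (n = 4). Of 36 cell-cycle genes, 35 fell and 0 rose (36 and 0 adjusted over the list alone, adjusted p = 0.300 with an estimated correlation), Bub1 by −3.68 ± 0.56. Cholesterol synthesis (16 of 17 fell, 16 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation) and glycolysis (14 of 16 fell, 14 adjusted over the list alone, adjusted p = 0.0742 with an estimated correlation) fell too, Sqle by −2.50 ± 0.17 and Pgk1 by −2.42 ± 0.13. Pdcd1 changed by −3.92 ± 0.36, Il2ra by −3.33 ± 0.35 and Gzmb by −2.69 ± 0.35, whereas Ifng rose by 3.25 ± 0.31, Ccl5 by 3.07 ± 0.24 and Il6ra by 3.02 ± 0.18. Of 22 interferon-stimulated genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation), Ifit3 by 3.57 ± 0.26 (also 3.57 counted from background).

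Rises after transfer took in the macrophage and monocyte genes Adgre4 (6.89 ± 1.07), Slc40a1, an iron exporter gene (6.38 ± 1.36), and Mrc1 (6.16 ± 1.14). All 3 lay under the background of 7.32 at 72 h, and counted from it they rose by 5.28, 5.73 and 5.06. Of 18 myeloid genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone, adjusted p = 0.342 with an estimated correlation). Of 19 NK-receptor genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 0.401 with an estimated correlation). Of 13 T-cell identity genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation). Of 15 B-cell markers, 8 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 0.196 with an estimated correlation). That list holds the MHC class II genes H2-Aa and H2-Eb1, at 10.35 and 9.98 at 72 h and 13.04 and 12.73 after transfer. Cd22 went from 7.29 to 8.59 and Blnk from 6.57, under background, to 9.40. Bank1, a B-cell gene outside the list, went from 7.22 to 10.75. But Ms4a1 (5.48 and 5.93) stayed under background, and Ighm (7.41 and 7.54) and Blk (7.15 and 7.12) moved little. The members moved unlike each other, so the count alone does not decide whether RNA from B cells was present. Of 19 immediate-early and heat-shock genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 0.369 with an estimated correlation). With the myeloid level as a covariate, Slc40a1 differed by 0.20 (adjusted p = 0.726) and Mrc1 by 1.09 (adjusted p = 0.103). Of 7476 genes, 2610 rose and 4866 fell, and of those changed at least 2-fold 1082 rose and 1102 fell. With that covariate 4135 were called.

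Stat5ca cells (n = 4) were compared with control cells (n = 2) after transfer for the effect of active Stat5 in cells that had persisted. The receptor gene Klra5 rose by 5.65 ± 0.21, the granzyme genes Gzma, Gzmb and Gzmk by 4.16 ± 0.41, 3.29 ± 0.35 and 3.25 ± 0.32, and Klrg1, a receptor of terminal effector cells, by 3.53 ± 0.41. Of 24 cytotoxic genes, 12 rose, 0 fell and 12 were not called (14 and 0 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation), and 12 of 17 Tc1 factor and receptor genes rose with 0 fallen (12 and 1 adjusted over the list alone, adjusted p = 0.250 with an estimated correlation), among them Eomes (1.78 ± 0.44) and Tbx21 (0.71 ± 0.15). Of 19 NK-receptor genes, 9 rose and 1 fell (9 and 4 adjusted over the list alone, adjusted p = 0.636 with an estimated correlation). Stat5a rose by 1.44 ± 0.13 and Stat5b changed by −0.36 ± 0.12. In controls Klra5 (5.54) and Klrg1 (6.99) lay under the background of 7.32, and counted from it they rose by 3.87 and 3.20. Eomes (1.37) and Tbx21 (0.59) no longer passed without the day 120 control, nor did Stat5b without the day 18 control (−0.23) or Stat5ca array 11 (−0.37), 12 (−0.35) or 13 (−0.33).

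Of 26 STAT5 target genes, 16 rose and 1 fell after transfer (19 and 1 adjusted over the list alone, adjusted p = 0.257 with an estimated correlation). Socs2 rose by 3.16 ± 0.39, Cish by 2.79 ± 0.19 and Il2ra by 2.99 ± 0.35, while Socs3 differed by 0.10 ± 0.34 (adjusted p = 0.866). Cell-cycle genes rose in 20 of 36 cases with 0 fallen (26 and 0 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation), Mcm5 by 1.19 ± 0.19. Of 20 ribosome-biogenesis genes, 15 rose with 0 fallen (16 and 0 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation). Il7r changed by −1.32 ± 0.20, Il6st by −1.41 ± 0.17 and Maf by −2.43 ± 0.38. T-cell identity genes rose in 10 of 13 cases (11 adjusted over the list alone, adjusted p = 0.300 with an estimated correlation), Cd3d by 1.13 ± 0.16, and 6 of 18 myeloid genes fell with 0 risen (7 and 0 adjusted over the list alone, adjusted p = 0.366 with an estimated correlation). The myeloid list averaged 9.42 to 10.11 in Stat5ca arrays against 11.69 and 11.93 in controls. Maf moved with that list, at 7.88 in control cells at 72 h and 11.52, 9.09 and 11.12 in transferred control, Stat5ca and T-betKO cells. For Maf, a smaller share of myeloid RNA can therefore not be told apart from an effect of Stat5ca. With the myeloid level as a covariate, 23 named results of this comparison lost their call and 70 did not. That level did not overlap between the groups, so changes adjusted for it are extrapolated. Of 5058 genes, 3371 rose and 1687 fell, and of those changed at least 2-fold 258 rose and 689 fell. The count was 2716 without the day 120 control, 3032 without the day 18 control and 2997 with the myeloid level as a covariate.

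**Figure D3:**
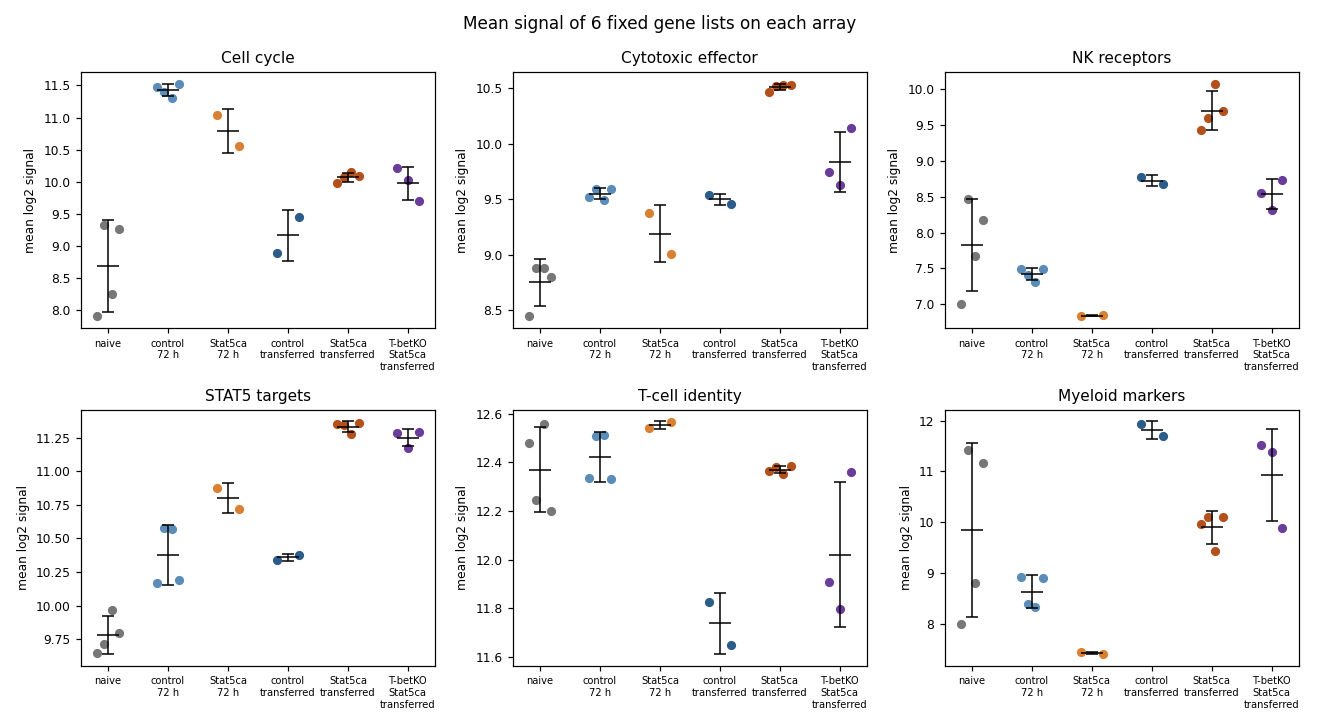
Mean log2 signal of 6 gene lists on each array by group; points are arrays, horizontal ticks are group means and bars are SD. Myeloid markers average 11.81 in transferred control cells and 9.90 in transferred Stat5ca cells, and cell-cycle genes average 11.43 in control cells at 72 h and 8.68 in naive cells.

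Stat5ca cells after transfer (n = 4) were compared with Stat5ca cells at 72 h (n = 2). Klra5 rose by 6.78 ± 0.21, Klrc1 by 6.41 ± 0.37, Gzma by 4.43 ± 0.41 and the chemokine receptor gene Ccr2 by 4.97 ± 0.38. At 72 h Klra5, Klrc1 and Ccr2 lay under the background of 7.32, and counted from it they rose by 3.87, 5.02 and 4.00. Of 24 cytotoxic genes, 12 rose and 0 fell (13 and 1 adjusted over the list alone, adjusted p = 0.0486 with an estimated correlation). This adjusted p was 0.0550 to 0.0639 without any 1 of the Stat5ca arrays after transfer, 0.106 with the myeloid covariate and 0.115 with the sex covariate. Of 19 NK-receptor genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation). Cholesterol-synthesis genes fell in 16 of 17 cases (17 adjusted over the list alone, adjusted p = 0.273 with an estimated correlation), and Lag3, an inhibitory receptor gene, changed by −3.16 ± 0.23, Cxcr5 by −3.70 ± 0.39 and Ikzf2 by −3.78 ± 0.34. Lyz2 rose by 5.33 ± 0.60 beside 9 of 18 myeloid genes that rose (13 adjusted over the list alone, adjusted p = 0.349 with an estimated correlation). Counted from background, Lyz2 rose by 4.34 and Cxcr5 changed by −2.25. Of 4243 genes, 1717 rose and 2526 fell, with 2144 and 2574 called without Stat5ca 72 h arrays 10 and 9 and 6790 with array weights.

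The effect of Stat5ca after transfer was then compared with its effect at 72 h. Gzma (6.02 ± 0.58), Klra5 (6.03 ± 0.30), Gzmk (4.28 ± 0.45) and Eomes (3.23 ± 0.62) had the more positive effect after transfer, and Ccr9 (−3.62 ± 0.56), Cxcr5 (−2.94 ± 0.56) and Jun (−2.85 ± 0.27) the more negative. With group means under background raised to 7.32, Klra5 differed by 3.87, Ccr9 by −3.23 and Cxcr5 by −1.49. For Stat5a the difference was −0.07 ± 0.18 (adjusted p = 0.870). Of 36 cell-cycle genes, 22 had the more positive effect after transfer and 0 the more negative (27 and 0 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation), and of 24 cytotoxic genes 11 and 0 (13 and 0 adjusted over the list alone, adjusted p = 0.0733 with an estimated correlation). T-cell identity genes moved the same way, 5 of 13 and 0 (7 and 0 adjusted over the list alone, adjusted p = 0.406 with an estimated correlation). In all, 3549 genes passed, 2456 more positive and 1093 more negative. By the labels only the Stat5ca cells at 72 h were sorted for GFP, so sorting cannot be told apart from a changed effect. With the myeloid level as a covariate, 86 named results of this comparison stayed on their side of the threshold, 1 gained it and 1 lost it. The count was 1985 and 2330 without Stat5ca 72 h arrays 10 and 9, 2225 without the day 120 control and 6096 with array weights.

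T-betKO Stat5ca cells (n = 3) were compared with Stat5ca cells (n = 4) after transfer for the part of T-bet. Tbx21 itself changed by −3.60 ± 0.13, to 8.24 ± 0.09, and Eomes by −0.38 ± 0.40 (adjusted p = 0.558). Il13 rose by 4.02 ± 0.42, Il5 by 3.36 ± 0.71 and the chemokine receptor genes Ccr4 and Ccr8 by 4.11 ± 0.21 and 3.90 ± 0.19. Of 22 cytokine and cytokine-receptor genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 0.0614 with an estimated correlation). Of 24 cytotoxic genes, 11 fell, 0 rose and 13 were not called (11 and 0 adjusted over the list alone, adjusted p = 0.273 with an estimated correlation). Gzmm changed by −2.92 ± 0.13. The falls also took in 9 of 17 Tc1 genes with 0 risen (10 and 0 adjusted over the list alone, adjusted p = 0.196 with an estimated correlation), with Cxcr3 at −1.87 ± 0.21. They took in 10 of 19 NK-receptor genes with 0 risen (10 and 1 adjusted over the list alone, adjusted p = 0.334 with an estimated correlation), with Klra5 at −4.19 ± 0.27. Counted from the background of 7.32, which Il5 and Ccr8 lay under in Stat5ca cells and Klra5 in T-betKO cells, the changes were 1.97, 3.25 and −3.87.

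Of 7 CD4 and regulatory T-cell marker genes, 3 rose and 0 fell in T-betKO cells (5 and 0 adjusted over the list alone, adjusted p = 0.0486 with an estimated correlation): Cd40lg by 2.26 ± 0.12, Foxp3 by 1.79 ± 0.19 and Nrp1 by 1.73 ± 0.36. The adjusted p of the list was 0.0550 to 0.0639 without any 1 of the 4 Stat5ca arrays, 0.0688 without T-betKO array 39, 0.0627 without 39 and 40, 0.0565 with the myeloid covariate and 0.107 with the sex covariate. Stat5a changed by −0.75 ± 0.11. H2-Ea changed by −6.32 ± 0.41, and C57BL/6 mice carry a deletion in this gene. Counted from background, Cd40lg rose by 1.44 and H2-Ea changed by −5.68. Of 13 T-cell identity genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 0.535 with an estimated correlation), with list means of 11.91, 11.80 and 12.36 in T-betKO arrays 39, 40 and 41 against 12.35 to 12.39 in Stat5ca arrays. Ribosome-biogenesis genes fell in 10 of 20 cases (13 adjusted over the list alone, adjusted p = 0.378 with an estimated correlation). The myeloid list averaged 11.52, 11.38 and 9.89 in T-betKO arrays 39, 40 and 41, whose RNA integrity numbers were 7, 6 and 8 and whose days of recovery were 14, 14 and 54. In the same order Il13 stood at 12.69, 12.61 and 9.96, Il5 at 10.99, 10.63 and 6.26, and Retnla, a gene of alternatively activated macrophages, at 12.67, 12.52 and 6.92. Of 4155 genes, 1401 rose and 2754 fell, and of those changed at least 2-fold 401 rose and 125 fell. The count was 1790 and 2614 without arrays 40 and 39, 715 without both, 1379 with the RNA integrity number as a covariate and 6870 with array weights. Without arrays 39 and 40, Il5 (0.33, adjusted p = 0.307), Il10 (0.51, adjusted p = 0.243), Retnla (0.89, adjusted p = 0.572) and Nrp1 (1.13, adjusted p = 0.247) no longer passed, while Il13 (2.23), Ccr4 (4.04) and Ccr8 (4.10) did. Of 77 named results, 45 lost their call and 1 reversed without these arrays, and 34 lost it with the RNA integrity covariate, Il5 (1.99) and Nrp1 (1.53) among them.

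Across all 8 comparisons, 2 of 200 list tests passed with an estimated correlation, the cytotoxic list in Stat5ca cells between 72 h and transfer and the CD4 and regulatory T-cell list in T-betKO cells. Neither passed without any 1 of Stat5ca arrays 11 to 14, and 0 of 200 tests passed with the myeloid or the sex covariate (41 and 31 at an unadjusted p under 0.05). Camera passed 96 with its preset correlation of 0.01, and these 2 were among them; the other calls did not hold with the estimated correlation. The direction test of fry passed 103.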

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

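The groupings and lists were planned, but the tests of explanations given here, the genes and limits they use and the comparison of splits of the arrays were all set down only after the results were seen. A first form of the NK-cell test used 4 receptor genes picked from those that had not risen, and was dropped for that reason. The limit in the T-cell share test was raised from 2 to 3 standard errors after its value was known; at 2 the value lay just past the limit and would have counted against that explanation.

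Values of single arrays were compared with the others of their group, and chance alone picks out about 1 group in 20. Of 84 group values tested for lists and transcription factors, 4 had an array far from the rest. Stat5a in control 72 h array 4 was 10.50 against 10.57 to 10.59. Stat5ca array 13 after transfer stood apart in the means of the interferon-stimulated list (9.45 against 9.78 to 9.82), the immediate-early and heat-shock list (10.58 against 11.24 to 11.26) and the erythroid list (8.43 against 9.69 to 9.76). Among named genes, 70 of 942 groups of values (7.43%) had such an array. It was naive array 33 for 7 genes, 34 for 0, 35 for 5 and 36 for 0, control 72 h arrays 1, 2, 3 and 4 for 1, 3, 3 and 2, and Stat5ca arrays 11, 12, 13 and 14 after transfer for 0, 1, 46 and 2.

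The difference between Stat5ca and control cells was not the same after transfer as at 72 h in 3549 genes. The differences were 6.03 in Klra5, 6.02 in Gzma, 4.28 in Gzmk, 4.28 in Klrc1, 4.12 in Lyz2, 3.73 in H2-Ea, 3.63 in Gpnmb and 3.60 in Klrg1. In the other direction they were −3.99 in Serpinb1a, −3.62 in Ccr9, −3.41 in Vsig4, −3.31 in Hpgds, −3.06 in Bank1, −2.95 in Prg4, −2.94 in Cxcr5 and −2.88 in Rhob. With group means under the background of 7.32 raised to it, they were 3.87 in Klra5, 2.88 in Klrc1, 3.14 in Lyz2, 3.23 in H2-Ea, 3.20 in Klrg1, −3.23 in Ccr9, −1.61 in Vsig4, −2.87 in Hpgds, −2.96 in Bank1, −1.68 in Prg4, −1.49 in Cxcr5 and −2.42 in Rhob. Gpnmb averaged 11.31 in control and 7.98 in Stat5ca cells at 72 h, and 7.68 and 7.98 after transfer. The myeloid list was lower in Stat5ca than in control arrays both at 72 h (7.43 against 8.635) and after transfer (9.90 against 11.81). Whether myeloid RNA accounts for the differences in Lyz2 and H2-Ea was not tested. Sorting for GFP, named only for Stat5ca cells at 72 h, cannot be told apart from a changed effect of Stat5ca.

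Other splits of the arrays were counted for the comparisons with at least 3 arrays a group. For control effector cells against naive cells, 1 of 35 splits, the real one, gave 9334 genes, and the highest other gave 90. That other split set control arrays 1 and 4 and naive arrays 34 and 36 against the rest. For T-betKO against Stat5ca cells after transfer, 1 of 35 splits, the real one, gave 4155 genes and the highest other gave 5. Splits that mix the groups put the group difference into the spread, which by itself lowers their counts. Whether the arrays of a group are separate replicates is also not known, so these counts do not exclude chance in either comparison.

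Naive arrays 34 and 36 stood apart from 33 and 35, with the myeloid list higher by a median of 2.55 (SD 1.74), the feature by which they were noticed. RNA integrity argues little for the split, since the lowest number of the first pair minus the highest of the second was 0. Array medians over the tested genes differed by 0.0586 between the pairs, which argues little for scaling. Over all probe sets, the medians were 7.84 and 7.86 in arrays 34 and 36 and 7.89 and 7.80 in arrays 33 and 35. T-cell identity genes, which had not been used to pick the arrays, were lower by a median of −0.29 (SD 0.12), 12 of 13 of them in both arrays, so RNA from myeloid cells is a candidate explanation. Cell-cycle genes (31 of 36, median 1.08) and NK receptors (13 of 19, 0.85) were also higher in both, and interferon-stimulated genes (17 of 22, −0.49, SD 0.22) and ribosome-biogenesis genes (10 of 20, −0.26, SD 0.12) lower, shifts that explanation was not tested on. The design names no difference between these arrays, and no biological explanation was tested.

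Of 43 killer-cell genes in the cytotoxic and NK-receptor lists, 21 were called higher in Stat5ca cells than in control cells after transfer, and neither list passed (adjusted p = 0.138 and 0.636). A larger share of T-cell RNA could raise them. Their median rise exceeded the largest rise of a T-cell identity gene (Cd3d, 1.13) by 0.67, about 2 standard errors of 0.33, in members picked for having risen. Under the raised limit this median does not decide for the 21 as a set. Of the 21, 15 rose by more than Cd3d, but this count takes no account of errors and does not decide for all 15. Gzma went from 8.70 to 12.86, Gzmb from 10.37 to 13.66 and Gzmk from 8.27 to 11.52, against 10.31 to 11.43 for Cd3d. For these granzyme genes that argues against a larger share as the whole account. With the myeloid level as a covariate, 19 of the 21 were still called, with a median rise of 2.21 against 0.48 for T-cell identity genes. Whether that 0.48 is a share of T-cell RNA left in or an effect of Stat5ca was not tested. The covariate did not overlap between these groups (9.42 to 10.11 in Stat5ca arrays, 11.69 and 11.93 in controls), so both adjusted rises are extrapolated. Within groups it varied most among the naive arrays (SD 1.71, against 0.17 in transferred control and 0.32 in transferred Stat5ca arrays). RNA from NK cells cannot be told apart from expression by the T cells, since Ncr1, an NK-cell gene, differed by −0.27 ± 0.65 from a level of 9.34 that would hide a small share; the labels call the cells purified CD8 T lymphocytes, which should remove NK cells, and name no gate. The effect of Stat5ca itself stays open beside these, as do transduction and the days of recovery.

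In T-betKO Stat5ca cells 7 genes of type-2 responses and CD4 T cells were higher (Il13, Il5, Il4, Il10, Ccr4, Ccr8 and Cd40lg). They were picked after their values were seen and form no planned list. Gata3, a factor of type-2 T cells, did not rise, at 11.32 in Stat5ca and 11.29 in T-betKO cells. Arrays 39 and 40 carry most of the cytokine rise. In array 41 Il5 (6.26) and Il10 (6.16) lay under background and Il4 stood at 7.44, against 8.38 to 10.99 for these 3 in arrays 39 and 40. RNA from myeloid cells like those in transferred control arrays is argued against, since these arrays, with as high a myeloid level, differed from Stat5ca arrays by a median of −0.21 (SD 0.44) in those genes, against a smallest change of 1.33 in T-betKO cells; 5 of the 7 lay under background in both, and counted from it the T-betKO changes of Il10 (0.42) and Il4 (0.96) are too small to argue from, so for these, and for other myeloid cells, it stays open. RNA from CD4 T cells, which purification should also remove, cannot be told apart. Cd4 differed by 0.71 ± 0.28 (adjusted p = 0.0806) and Zbtb7b by 0.27 ± 0.25 (adjusted p = 0.511) from levels above background. Transferred control arrays had Cd4 at 9.51 and Zbtb7b at 9.48, against 8.99 and 9.10 in T-betKO arrays. They showed no like rise in Il13, Il5, Ccr4, Ccr8 or Cd40lg. But Cd4 moved with the myeloid list, at 7.26 in control cells at 72 h and 8.27 in Stat5ca cells after transfer. The control arrays therefore need not hold CD4 T cells, and the lack of a rise in them does not decide. Strain, stimulus or labelling batch cannot be told apart from the loss of T-bet, because 0 of the 3 T-betKO arrays share a labelling protocol with any other array. The loss of T-bet may therefore account for the rise, untested against these.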

How the results depend on the processing

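The myeloid and sex covariates and the fits without 2 arrays were chosen after seeing the data; the others were planned. The cause was not tested unless stated. By construction, a 2-fold minimum left 1425 genes for control 72 h against naive cells, 183 for Stat5ca at 72 h, 742 for transferred against naive, 2184 for transferred against 72 h, 947 for Stat5ca after transfer, 992 for Stat5ca over time, 1121 for the difference of effects and 526 for T-betKO. Array weights gave 4604 for Stat5ca at 72 h, 6790 over time, 6096 for the difference of effects and 6870 for T-betKO. The RNA integrity covariate gave 1379 for T-betKO, and the contrasted groups alone 323 for transferred against naive. The myeloid covariate gave 799, 4135 and 2997 for transferred against naive, transferred against 72 h and Stat5ca after transfer. Without naive arrays 34 and 36, or 33 and 35, transferred against naive had 5767 and 1718, and without T-betKO arrays 39 and 40 that comparison had 715.

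Leaving out 1 array gave 98 to 1794 for Stat5ca at 72 h (98 without Stat5ca array 10, 463 without 9), 840 to 4693 for transferred against naive (840 without the day 120 array), 2716 to 4472 for Stat5ca after transfer, 2144 to 3844 for Stat5ca over time, 1985 to 3806 for the difference of effects and 1790 to 5237 for T-betKO (1790 without array 40). A lone remaining array was taken to vary like the other groups. Activation (7707 to 9923) and transferred against 72 h (5473 to 7396) stayed within 1.5 times. List tests passing were 96 with a preset correlation, 103 with fry, 0 with the myeloid covariate (camera; 41 at an unadjusted p under 0.05) and 0 to 4 of 200 without 1 array, comparisons lacking that array being left as they were; among the tests fitted again 0 to 2 passed. With the myeloid covariate, Ltf (−0.75), S100a8 (−2.05) and S100a9 (−1.69) reversed in transferred against 72 h. S100a8 and S100a9 belong to the list behind the covariate, so their adjustment is circular. The covariate also did not overlap between these groups (8.33 to 8.91 at 72 h, 11.69 and 11.93 after transfer), so changes adjusted for it are extrapolated. The same holds for Stat5ca against control after transfer (9.42 to 10.11 against 11.69 and 11.93). Without T-betKO arrays 39 and 40, Hspa1a was −0.0372. Of 5061 named-gene results without 1 array, 4467 stayed on their side of the threshold, 589 lost it, 5 gained it and 0 reversed; with the myeloid covariate 582 of 710 stayed. The sex covariate is coarse, since some arrays held RNA of both sexes. Genes under the background of 7.32 could hide changes.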

Other observations

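The comparison of genes shared between the Stat5ca and T-betKO results was chosen after those results were seen. Of 3371 genes that rose with Stat5ca after transfer, 1834 fell in T-betKO Stat5ca cells, against 466 for independent lists, and 20 rose, against 237. Of 1687 that fell with Stat5ca, 779 rose in T-betKO cells, against 119. All 9 NK-receptor genes that rose with Stat5ca fell in T-betKO cells, as did 9 of 12 cytotoxic genes, 8 of 12 Tc1 genes and 9 of 15 ribosome-biogenesis genes. Of 20 cell-cycle genes 2 fell, and of 16 STAT5 targets 7 fell and 2 rose; differences between lists were not tested. The Stat5ca arrays after transfer stand in both comparisons, which alone gives opposite changes. Across genes, which are not independent replicates, the changes had r = −0.74, and data simulated without effects gave −0.38. With the 4 shared arrays split so that each comparison used its own 2, r lay between −0.73 and −0.67 over 6 splits, and 622 to 749 genes rose and then fell, against 104 to 151 for independent lists. The split removes only what differs between these 4 arrays. They share a day of recovery and may not be separate replicates. Anything common to them stays in both comparisons and by itself gives opposite changes. The myeloid level, lower on average in Stat5ca arrays (9.90) than in control (11.81) and T-betKO arrays (10.93), moves with both comparisons. So does Stat5a, at 11.54 to 11.81 in Stat5ca arrays, 10.03 and 10.46 in control arrays and 10.86 to 11.06 in T-betKO arrays. A lower level of Stat5ca in T-betKO cells can therefore not be told apart from the loss of T-bet in this overlap.

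At 72 h and after transfer the Stat5ca effects shared fewer genes. Of 472 genes that rose at 72 h, 101 rose after transfer, against 79.8 for independent lists, and 53 fell, against 39.9. Of 668 that fell at 72 h, 281 rose after transfer, against 113, and 58 fell, against 56.5. Across genes the changes had r = 0.12, and no array was shared.

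Control 72 h arrays 1 and 4 differed from 2 and 3 in the cholesterol-synthesis list, which averaged 10.28 and 10.35 in the first pair and 11.13 and 11.01 in the second. The first pair carried Y-linked RNA (Eif2s3y at 10.62 and 10.77) and the second Xist (12.92 and 12.84). Some arrays carried both. Transferred control array 30 had Xist at 12.22 and Eif2s3y at 9.64, Stat5ca array 13 after transfer 10.09 and 10.44, and Stat5ca 72 h array 10 12.52 and 9.29. T-betKO array 39 had 12.25 and 9.24, and array 40 had 12.26 and 8.72. Naive array 35 had 12.65 and 7.87, against Eif2s3y at 4.75 to 5.08 in the other naive arrays.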
